A study of Mus musculus with 6 samples.

How the data were processed

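RNA was measured in 6 mouse libraries: biopsies of healthy skin (1 library), papilloma (2) and tumour (1), and the cultured cells mSCC-20 (1) and mSCC-38 (1). Per the labels' protocols, total RNA was extracted in Qiazol, purified with a column kit that keeps small RNA, and made into libraries with a small RNA kit for SOLiD sequencers. The RNA integrity numbers in the labels were 7.5 for skin, 8.4 and 8.2 for papilloma 1 and papilloma 2, 9.1 for the tumour, 9.3 for mSCC-20 and 9.6 for mSCC-38. The labels name the papillomas as distinct but do not say whether they came from separate mice, so p-values measure only the spread between these samples, which may be technical in part.

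The authors deposited 1 table with 23726 gene models, each with RefSeq transcripts, a position, a length, a raw count per library and an RPKM value per library. The reads had been assigned to genome build mm9, per the submitters' processing notes. The aligner, the counting program and its use of strand are not given in the sources used here, so reads of overlapping, antisense and near-identical genes could not be separated. Per the file headers and the values, the count columns hold whole raw counts without normalisation. The deposited RPKM values equal the count divided by the gene length and by a total that was 99.2% to 99.6% of the summed counts of each library; they were used only to check the counts. Of the gene models, 19362 had a count in at least 1 library and 4364 had none. Models named as duplicates numbered 1099, and 51 repeated another model's name and were kept apart. Of 15512 models with a total of at least 60 counts, 45 carried the same counts as another model. The 792 microRNA models took at most 0.0271% of a library's counts, so the table describes long transcripts despite the small RNA kit, and no mitochondrial chromosome was listed.

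Total counts ranged from 25140489 in papilloma 1 to 42992597 in the tumour. A count of 0 allows up to 3 counts, which are 0.0604, 0.141, 0.106, 0.0710, 0.0975 and 0.0902 CPM in skin, papilloma 1, papilloma 2, tumour, mSCC-20 and mSCC-38. The 10 most counted genes took 4.55%, 11.4%, 9.02%, 7.50%, 4.07% and 3.07% of the counts, and genes with a count numbered, in the same order, 18223, 17236, 17612, 17814, 15414 and 15571. Values in CPM (counts per 1000000 counts) were scaled with TMM factors of 1.20, 0.847, 0.942, 0.983, 0.991 and 1.07. Ratios in CPM had 0.5 CPM added to each side on the log2 scale. The 95% intervals of ratios are exact Clopper-Pearson intervals, and intervals and floors cover counting error only. In papilloma 1, the tumour and both cultures, 17 hair genes with at least 500 CPM in skin were still counted at a median of 0.0438% to 0.0669% of the skin level, with upper quartiles of up to 0.0855%. A level at or under 0.0855% of the gene's highest library was therefore read as background, so that a ratio from it is not exact and a larger difference would read alike, a rule set after the data were seen.

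Papilloma was compared with skin, and tumour with papilloma, by edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3, default legacy method, TMM, default filter on low counts by group). The 4 biopsy libraries were fitted together over 16353 genes, and the 2 papillomas gave the 1 residual degree of freedom (common dispersion 0.0773, prior degrees of freedom 3.81, total 4.81). The fit takes skin and tumour to vary as the papillomas do, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was worked back from the test, as its absolute value divided by the square root of edgeR's F statistic. It therefore holds no information beyond the fold change and that test. At an unadjusted p under 0.05 the fit gave 7113 genes for papilloma against skin and 6297 for tumour against papilloma. Tumour against skin and mSCC-38 against mSCC-20 have 1 library per side and were described by a rule of size, a ratio of at least 4-fold with at least 10 CPM in the higher group, without a p-value. Tested on simulated data of 16353 genes, the edgeR step recovered 72% of 100 genes changed 4-fold and 97% of 100 changed 16-fold for papilloma against skin, with 12 of 181 calls false. For tumour against papilloma it recovered 75% and 98%, with 10 of 183 calls false. The simulation gave all 4 biopsy libraries the same mean per gene, apart from 200 changed genes. It took dispersions from the fit's trend over abundance, so genes of like abundance did not differ in dispersion. Real genes can differ, so the recovered shares may not carry over to them. The simulation also cannot test whether skin and tumour vary as the papillomas do. With so few changed genes, its share of false calls does not carry over to the real calls.

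The design, the rule for named genes, 35 gene lists and the alternatives were fixed before the data were examined. Named genes were the 12 highest and 12 lowest per comparison: in the tested comparisons by edgeR's fold change among called genes with at least 10 CPM in the higher group and both papillomas on the same side, in the others by ratio among genes with at least 20 CPM in the higher group. Unnamed gene models and small RNAs were passed over, and some genes that the rule named are not reported here. For examples of a list the rule had named its 4 members of largest fold change; the examples given do not all follow it and were chosen after their values were seen. Of the 444 genes in the lists, 432 matched by the same symbol, 8 by another symbol and 4 not at all. The lists cover keratinocytes (basal, differentiation, stress, simple and mucosal keratins, junctions), other skin cells (hair, sebaceous gland, adipocyte, muscle, melanocyte, endothelial, fibroblast, erythrocyte), immune cells, and programmes of growth, stress and signalling. For each list the median log2 ratio of the members with a mean of at least 1 CPM was set against 10000 random lists of the same size, matched on mean CPM in 20 bins; its percentile describes these libraries. Lists with fewer than 3 such members have no median. The alternatives were DESeq2's size factors, total counts alone, no filter on low counts, DESeq2's Wald test (DESeq2 1.42.0), edgeR without its legacy method, other sets of libraries in the fit, other limits of the size rule, and each papilloma left out. Values outside edgeR and DESeq2 were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.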

Results

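RNA was sequenced from 6 mouse libraries that follow skin carcinogenesis by DMBA, a mutagenic hydrocarbon, and TPA, a phorbol ester that drives keratinocyte growth. Painting skin with these compounds gives benign papillomas, some of which progress to squamous cell carcinoma. The biopsies were 1 healthy skin, 2 separate papillomas and 1 tumour. The cultured samples were mSCC-20 and mSCC-38, each cultured from a DMBA/TPA tumour, which the submitters describe as non-tumorigenic and highly tumorigenic. The labels do not say whether both came from the same tumour or mouse. Total counts were 41462120 for skin, 25140489 for papilloma 1, 29982455 for papilloma 2 and 42992597 for the tumour. The cultures had 31045938 (mSCC-20) and 30955914 (mSCC-38) counts. The basal keratin gene Krt14 was the most counted gene in both papillomas and in the tumour, Tchh, which encodes a hair root sheath protein, in skin, Krt5 in mSCC-20 and Vim in mSCC-38. Correlations of log2 (CPM + 1) were taken across 13985 genes with a mean of at least 1 CPM, which are not independent replicates. Pearson's r was 0.963 between the papillomas and 0.735 between skin and tumour. The counts of the papillomas differed by more than counting noise, with a chi-square of 79.1 per degree of freedom over 14845 genes. This shows that they are not 1 library listed again, and nothing of whether they are biological replicates, for which the labels' word that they are distinct was taken. Only papilloma has more than 1 library, so values of skin, tumour and the cultured cells carry no replicate error. Genes named as examples of a list were chosen after their values were seen.

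The comparison of papilloma with healthy skin asks how the benign lesion differs from the tissue it grew in. Of 15 stress keratin and cornified envelope genes, which injured epidermis induces, 13 rose in the papillomas and 0 fell. Krt6b, a keratin induced in injured epidermis (chromosome 15, 101506455 to 101510720, mm9), was at 29.4 CPM in skin and at 16758 ± 5105 CPM in papilloma (SD, n = 2), a log2 fold change of 9.16 ± 0.77 (SE, edgeR adjusted p = 0.00654). Of 14 skeletal muscle genes 13 fell, among them the oxygen carrier gene Mb, with a log2 fold change of -3.74 ± 0.29 (edgeR adjusted p = 0.00578). edgeR's quasi-likelihood test called 1959 genes higher and 2298 lower in papilloma of 16353 tested, against 2352 and 1730 by DESeq2's Wald test. By the fixed rule of size, 392 genes were at least 4-fold higher and 552 at least 4-fold lower. Scaling by total counts alone gave 275 and 839, and moved the median log2 ratio of genes at 10 CPM or more from 0.07 to -0.37. The test rests on 1 residual degree of freedom, from the 2 papillomas, and takes the single skin library to vary as they do.

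The 12 called genes with the largest rises in papilloma included Spink7 and Htr1b. Spink7, which encodes a protease inhibitor of stratified epithelium (chromosome 18, 62752068 to 62755918), had 0 counts in skin and 25.8 ± 12.3 CPM in papilloma, at least 426-fold higher (edgeR adjusted p = 0.0068). The serotonin receptor gene Htr1b also had 0 counts in skin and was at least 184-fold higher (edgeR adjusted p = 0.00451). Oit1 had 1 count in skin and a ratio of counts per library size of 1254 (95% interval 225 to 49554). The skin values of Oit1 and Defb3 were 0.0547% and 0.0777% of their highest library, within the background of up to 0.0855%, so neither ratio is exact and larger rises would read alike. Defb3, an antimicrobial peptide gene, rose from 0.101 to 95.97 ± 47.5 CPM, and the phospholipase gene Pla2g4d from 0.222 to 160.2 ± 69.9 CPM. Serpinb3a, a protease inhibitor gene, and Tmprss11d, a membrane protease gene, had the same log2 fold change to 2 decimals, 9.37, with SE 0.40 and 0.70. The cornified envelope genes Sprr2k, Sprr2j-ps and Sprr3 rose by log2 fold changes of 9.63, 9.49 and 9.42. Skin values of Sprr3, Sprr2k, Sprr2j-ps, Pla2g4d and Tmprss11d lay just above the background. They ran from 0.0873% of the highest library for Sprr3 to 0.113% for Tmprss11d. The background bound is an upper quartile, so these rises may not be exact either. Log2 ratios (0.5 CPM added to each side) with both papillomas, without papilloma 1 and without papilloma 2 were, in that order, for Defb3 7.33, 7.76 and 6.71; Sprr2k 8.47, 7.71 and 8.97; Sprr2j-ps 8.26, 7.66 and 8.68; and Sprr3 8.82, 7.22 and 9.56. Reads of the Sprr2 family, of Krt6b and of Serpinb3a could be split among near-identical copies, so these values are uncertain as single-gene values.

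The 12 called genes with the deepest falls in papilloma were led by Hamp2 and Mrgprb3. Hamp2, of the hepcidin family, fell from 39.4 to 0.27 ± 0.282 CPM, a log2 fold change of -7.28 ± 0.70 (edgeR adjusted p = 0.00796). Hsd11b2, which encodes a glucocorticoid-inactivating enzyme, fell from 14.8 to 0.347 ± 0.0403 CPM, and Lep, the adipocyte hormone leptin, from 17.1 to 1.15 ± 0.828 CPM. Cxcl13, a B cell chemoattractant, was at 16.6 CPM in skin and 0.989 ± 0.00365 CPM in papilloma, and the epidermal gene Skint10 at 73.7 and 4.22 ± 0.409 CPM. Mrgprb3, Ifitm6, Serpinb6e, Scd3, Nnat, Hspb7 and Kcne1 completed the 12 deepest, with log2 fold changes between -5.60 for Mrgprb3 and -3.79 for Hspb7. Kcne1 had 11.5 CPM in skin, 0 counts in papilloma 1 and 0.743 CPM in papilloma 2, and its call (edgeR adjusted p = 0.039) was lost with DESeq2's size factors; without papilloma 2 it was at least 81.6-fold lower, and without papilloma 1 its log2 ratio was -3.27. The log2 ratios with both papillomas, without papilloma 1 and without papilloma 2 were for Lep -3.42, -2.98 and -4.05.

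Each of the keratinocyte lists held more rises than falls in papilloma, while in the same libraries 13 of 14 skeletal muscle genes and 9 of 12 adipocyte genes fell. Of 15 tested stress keratin and cornified envelope genes, 13 rose and 0 fell over all genes (14 up and 0 down adjusted over the list alone; median log2 ratio 6.30, percentile 100 of random lists). Krt16 rose from 40.7 to 9699 ± 3707 CPM, and S100a9, which encodes a calprotectin subunit, from 7.09 to 1808 ± 281 CPM. Of 12 basal keratinocyte genes, 7 rose and 2 fell (7 up and 2 down adjusted over the list alone; median log2 ratio 1.53, percentile 99.5). Krt14 rose by 3.51 ± 0.58 on the log2 scale (edgeR adjusted p = 0.0196). Krt15, a keratin of the hair bulge and basal layer, fell to 174 ± 43.5 from 1344 CPM. Krt5, the partner of Krt14, was at 3363 CPM in skin and 7256 ± 993 CPM in papilloma and did not pass (edgeR adjusted p = 0.111), although it passed with total-count scaling. In the epidermal differentiation list 10 of 19 genes rose and 3 fell (12 up and 3 down adjusted over the list alone; median log2 ratio 1.34, percentile 99.4). Krt1 and Casp14, a protease gene of cornification, rose by 2.88 ± 0.42 and 3.47 ± 0.30, while Lce1m was at -2.86 ± 0.24. Simple and mucosal keratins went both ways, with 2 up and 1 down of 8 (2 up and 2 down adjusted over the list alone and 2 up and 0 down by DESeq2 over all genes; median log2 ratio -0.05, percentile 43.3; median 0.03 without papilloma 2). The mucosal keratins Krt13 and Krt4 rose from 2.20 and 1.31 CPM in skin to 1065 and 96.7 CPM in papilloma 1 and 236 and 21.6 CPM in papilloma 2, the skin value of Krt13 being at background (0.0475% of its highest library) and the call of Krt4 being lost with DESeq2's size factors. Log2 ratios with both papillomas, without papilloma 1 and without papilloma 2 were for Krt13 7.92, 6.45 and 8.63; and Krt4 5.04, 3.61 and 5.75. Among epithelial junction genes, 5 of 16 rose and 0 fell (7 up and 0 down adjusted over the list alone and 10 up and 0 down by DESeq2 over all genes; median log2 ratio 0.84, percentile 81.1), led by the desmoglein gene Dsg3 at 3.18 ± 0.35.

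Lists of growth, inflammation and stress genes held more rises than falls in papilloma. Of 17 inflammatory cytokine genes, 13 rose and 0 fell (14 up and 0 down adjusted over the list alone; median log2 ratio 2.91, percentile 100). The cytokine gene Il24 rose by 7.91 ± 0.37 on the log2 scale, and the chemokine gene Cxcl2, with 3 counts in skin, was 287-fold (95% interval 97.7 to 1392) higher. Skin values of Il24 and Cxcl2, 0.116% and 0.107% of their highest library, lay just above the background, so these rises may not be exact. Matrix protease and inhibitor genes rose in 9 and fell in 1 of 14 cases (9 up and 2 down adjusted over the list alone; median log2 ratio 1.96, percentile 100). The collagenase gene Mmp13 rose from 1.43 to 176 ± 66.95 CPM and Mmp9 from 4.71 to 177 ± 78.6 CPM. In the Ras MAPK output list 8 of 16 rose and 0 fell (9 up and 0 down adjusted over the list alone; median log2 ratio 1.72, percentile 100). The chromatin protein gene Hmga2 rose by 6.31 ± 0.26 and the EGF receptor ligand gene Hbegf by 4.35 ± 0.26 (edgeR adjusted p = 0.00383 and 0.00419). The proliferation list had 12 of 20 genes up and 0 down (16 up and 0 down adjusted over the list alone; median log2 ratio 0.87, percentile 100). The cyclin genes Ccnd1 and Ccne1 rose by 1.77 ± 0.26 and 1.74 ± 0.22. Hypoxia and glycolysis genes followed, with 7 of 14 up and 0 down (8 up and 0 down adjusted over the list alone; median log2 ratio 1.48, percentile 99.99). The glucose transporter gene Slc2a1 rose by 2.66 ± 0.26. For oxidative stress NRF2 genes the counts were 5 up and 2 down of 12 (9 up and 3 down adjusted over the list alone and 9 up and 2 down by DESeq2 over all genes; median log2 ratio 1.28, percentile 99.99). The glutathione transferase gene Gsta4 rose by 6.05 ± 0.71. With both papillomas, without papilloma 1 and without papilloma 2 the log2 ratios were for Gsta4 5.99, 5.31 and 6.45. AP-1 and immediate early genes had 3 up and 0 down of 11 (3 up and 0 down adjusted over the list alone; median log2 ratio 0.29, percentile 78.8; median -0.11 without papilloma 1), with Fos at 1.79 ± 0.25. The p53 target and cell cycle inhibitor list had 3 up and 0 down of 12 (3 up and 0 down adjusted over the list alone and 3 up and 1 down by DESeq2 over all genes; median log2 ratio 0.26, percentile 76.3). Cdkn2a, the p16 and p19 tumour suppressor gene, rose from 0.242 to 12.9 ± 1.56 CPM (edgeR adjusted p = 0.00383).

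Most lists of skin appendages and of the tissue under the epidermis held more falls than rises in papilloma. Skeletal muscle genes fell in 13 and rose in 0 of 14 cases (0 up and 13 down adjusted over the list alone; median log2 ratio -2.73, percentile 0). The myosin gene Myh1 fell from 2013 to 156 ± 28.7 CPM. Of 12 adipocyte genes, 9 fell and 0 rose over all genes (2 up and 10 down adjusted over the list alone and 1 up and 10 down by DESeq2 over all genes; median log2 ratio -2.72, percentile 0; median -2.13 without papilloma 1 and -3.26 without papilloma 2). Adipoq, encoding the hormone adiponectin, was at -3.19 ± 0.51 on the log2 scale. Sebaceous gland genes fell in 9 and rose in 0 of 12 cases (0 up and 10 down adjusted over the list alone; median log2 ratio -1.08, percentile 0.02). Among them was the wax synthase gene Awat2, at -3.10 ± 0.20. The papillomas differed from each other in hair genes: Krt71, an inner root sheath keratin, was at 4243 CPM in skin, 2.96 in papilloma 1 and 1460.3 in papilloma 2. Only 1 of 21 hair follicle and shaft genes passed the test as lower and 0 as higher (0 up and 1 down adjusted over the list alone), although the median log2 ratio was -2.92 (percentile 0), or -1.94 without papilloma 1 and -8.85 without papilloma 2, where hair genes lay at background level. The only gene of that list that passed was Foxn1, a transcription factor gene needed for hair keratinisation. Melanocyte genes had 0 up and 0 down of 8 by edgeR (0 up and 0 down adjusted over the list alone; 0 up and 0 down at an unadjusted p under 0.05, 0 and 0 by DESeq2; median log2 ratio -2.25, percentile 0; -1.36 without papilloma 1, -5.07 without papilloma 2). The pigment enzyme gene Dct was at 157, 4.32 and 48.5 CPM in skin, papilloma 1 and papilloma 2. Wnt genes had 1 up and 4 down of 12 (3 up and 5 down adjusted over the list alone and 2 up and 5 down by DESeq2 over all genes; median log2 ratio -1.46, percentile 0), with the Wnt target Axin2 at -1.84 ± 0.22. Hair follicle stem and tumour initiating genes had 2 up and 6 down of 11 (2 up and 7 down adjusted over the list alone; median log2 ratio -0.88, percentile 0.15). The transcription factor gene Pitx1 rose by 7.03 ± 0.55 and Lhx2 fell by 3.19 ± 0.59 on the log2 scale. In the order of both papillomas, without papilloma 1 and without papilloma 2, log2 ratios were for Adipoq -3.13, -2.63 and -3.90; and Lhx2 -3.14, -2.58 and -4.07.

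Immune and stromal lists held both rises and falls in papilloma. Neutrophil genes had 3 up and 1 down of 11 (3 up and 1 down adjusted over the list alone; median log2 ratio 2.14, percentile 99.97 over the 5 measured members). The chemokine receptor gene Cxcr2 rose from 1.35 to 37.5 ± 4.54 CPM. The neutrophil median was 0.67 with every member that had a count, 1.24 without papilloma 1 and 2.86 without papilloma 2. Of 13 T and NK cell genes, 5 fell and 1 rose (2 up and 5 down adjusted over the list alone and 0 up and 5 down by DESeq2 over all genes; median log2 ratio -1.41, percentile 1.48, and -0.67 with every member that had a count). The T cell receptor component gene Cd3e was at 10.9 CPM in skin and 1.90 ± 0.634 CPM in papilloma. The macrophage and monocyte list held 2 rises and 4 falls among 13 (3 up and 6 down adjusted over the list alone; median log2 ratio -0.41, percentile 3.0). Cd14 rose by 2.02 ± 0.24 and the complement gene C1qb fell by 1.35 ± 0.13. Interferon response genes had 4 falls and 0 rises among 14 (0 up and 4 down adjusted over the list alone and 0 up and 2 down by DESeq2 over all genes; median log2 ratio -0.70, percentile 11.5). The MHC class II and dendritic cell list had 2 rises and 0 falls among 10 (1 up and 0 down adjusted over the list alone and 1 up and 0 down by DESeq2 over all genes; median log2 ratio 0.12, percentile 79.8). In the mast cell list 2 rose and 0 fell among 9 (3 up and 0 down adjusted over the list alone and 2 up and 1 down by DESeq2 over all genes; median log2 ratio -0.06, percentile 73.3; median 0.08 without papilloma 1). The mast cell tryptase Tpsab1 rose from 0.644 to 14.3 ± 0.818 CPM. Erythrocyte genes had 2 up and 1 down of 6 (2 up and 1 down adjusted over the list alone; median log2 ratio 0.70, percentile 99.2). The risen globin genes Hbb-b1 and Hbb-b2 carry identical counts, stand for 1 signal, and lost their call with DESeq2's size factors and total-count scaling. Among B and plasma cell genes, 0 rose and 1 fell of 4 (0 up and 1 down adjusted over the list alone), against 0 up and 0 down by DESeq2. Fibroblast and fibrillar matrix genes had 2 up and 3 down of 13 (3 up and 3 down adjusted over the list alone; median log2 ratio 0.48, percentile 65.6), against 5 up and 3 down by DESeq2. Postn, a matrix protein gene, was at 1.79 ± 0.27 and the proteoglycan gene Dcn at -1.83 ± 0.24. Endothelial genes had 1 up and 2 down of 10 (1 up and 2 down adjusted over the list alone; median log2 ratio 0.04, percentile 64.6; median -0.05 without papilloma 1).

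The remaining lists held few calls in papilloma against skin. Mesenchymal and EMT genes (epithelial to mesenchymal transition) had 0 up and 3 down of 14 (0 up and 3 down adjusted over the list alone; median log2 ratio -0.18, percentile 7.83). DESeq2 called 3 up and 2 down in that list. By edgeR the repressors of epithelial genes Zeb1 and Zeb2 were among the fallen, although the call of Zeb1 was lost with DESeq2's size factors. In the same libraries 5 of 13 T and NK cell genes and 4 of 13 macrophage and monocyte genes also fell. Of 9 Notch genes, 0 rose and 1 fell (0 up and 0 down adjusted over the list alone; median log2 ratio -0.27, percentile 2.96). The fallen gene was Rbpj, the pathway's DNA-binding factor, whose call was lost with DESeq2's size factors, and DESeq2's Wald test called 1 up and 0 down. The immune checkpoint and antigen presentation list had 0 up and 0 down of 11 by edgeR (0 up and 0 down adjusted over the list alone; median log2 ratio -0.28, percentile 3.90). It had 1 up and 2 down at an unadjusted p under 0.05, 0 and 0 by DESeq2. Cd274, encoding PD-L1, was at 11.4 CPM in skin and 12.1 ± 1.78 CPM in papilloma. Xist, expressed from the inactive X chromosome of females, was at 985 CPM in skin and 887 ± 156 CPM in papilloma, and of the 2 sex linked genes tested 0 rose and 0 fell by edgeR (0 up and 0 down adjusted over the list alone; 0 up and 0 down at an unadjusted p under 0.05, 0 and 0 by DESeq2). Of the skin microRNA list, 2 precursor genes had enough counts for edgeR, and 0 rose and 0 fell (0 up and 0 down adjusted over the list alone; 0 up and 0 down at an unadjusted p under 0.05, 0 and 0 by DESeq2): Mir21 was at 0.161 CPM in skin and 0.259 ± 0.0342 CPM in papilloma. Of the lists, 11 of 32 measured ones lay above the central 95% of random lists and 8 below it. For lists of genes drawn independently 1.6 would lie outside, but genes of a list can vary together and skin had 1 library. The counts therefore give no significance.

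**Figure D1:**
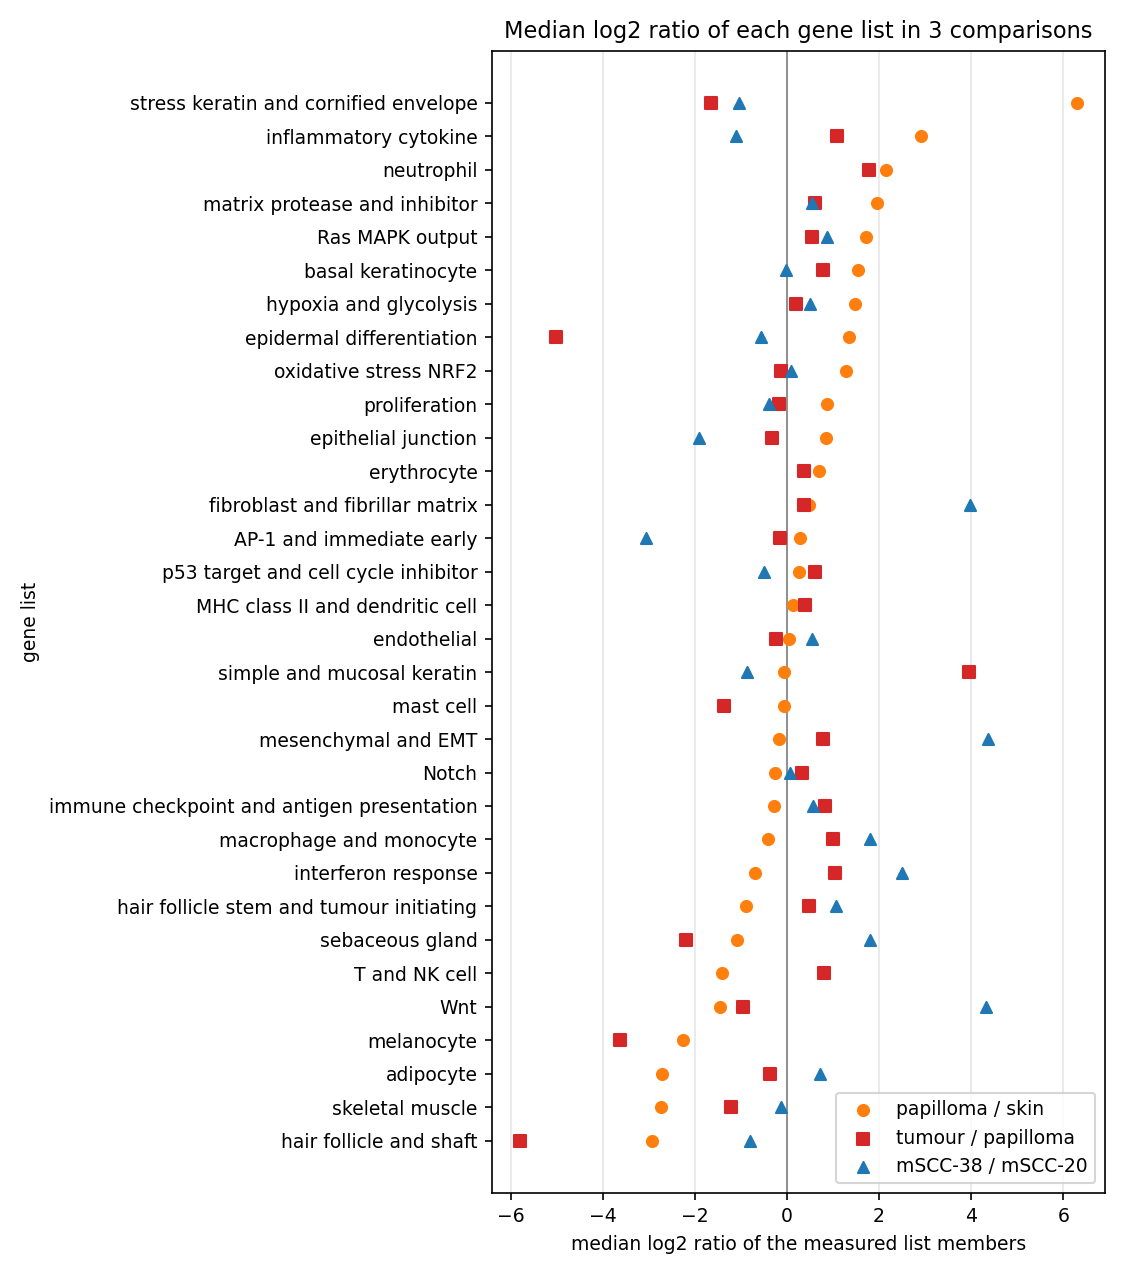
Median log2 ratio of each gene list (x axis; 1 row per list on the y axis) for papilloma against skin (circles), tumour against papilloma (squares) and mSCC-38 against mSCC-20 (triangles), with no error bars because the medians are over genes. The stress keratin and cornified envelope list lies at 6.30 in papilloma against skin and at -1.65 in tumour against papilloma; the epidermal differentiation list goes from 1.34 to -5.02.

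The comparison of tumour with papilloma asks what sets the malignant lesion apart from the benign one. Of 19 epidermal differentiation genes 15 fell in the tumour, while 4 of 8 simple and mucosal keratin genes rose and 1 fell. Krt1, the suprabasal keratin gene (chromosome 15, 101675858 to 101681217), fell from 10032 ± 357 CPM in papilloma (SD, n = 2) to 96.6 CPM in the tumour, a log2 fold change of -6.70 ± 0.52 (edgeR adjusted p = 0.00369). Krt19, a keratin of simple and ductal epithelia (chromosome 11, 100002127 to 100007233), rose from 1.88 ± 0.259 to 371 CPM, a log2 fold change of 7.62 ± 0.22 (edgeR adjusted p = 0.00205). edgeR's test called 1954 genes higher and 1733 lower in the tumour of 16353 tested. DESeq2's Wald test called 1796 higher and 1905 lower, so which direction held more calls depended on the tool. The size rule gave 274 genes at least 4-fold higher and 536 at least 4-fold lower. With 1 tumour library, these calls compare that tumour with the papillomas and assume that tumours vary as papillomas do. Total-count scaling moved the median log2 ratio of genes at 10 CPM or more from 0.03 to 0.17.

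The 12 called genes with the largest rises in the tumour over papilloma included Serpinb9f and Muc4. Serpinb9f, of a granzyme inhibitor family (chromosome 13, 33415947 to 33427235), had 0 counts in both papillomas and 15.9 CPM in the tumour, at least 128-fold higher with 3 counts set per papilloma library. The membrane mucin gene Muc4 had 3 counts over both papillomas and was 492-fold (95% interval 168 to 2388) higher. With 2 counts over both papillomas each, Lrrc26 was 541-fold (95% interval 149 to 4472), Serpinb9g 344-fold (95% interval 94.9 to 2849.6) and the intestinal antigen gene Gpa33 318-fold (95% interval 87.7 to 2636) higher. Ltf, which encodes the iron-binding protein lactoferrin, was at 12.3 and 2.34 CPM in papilloma 1 and papilloma 2 and at 2018 CPM in the tumour, with a log2 fold change of 8.11 ± 1.04 (edgeR adjusted p = 0.0101). Tspan1, Slc44a4, a choline transporter family gene, Adamdec1, a secreted protease gene, and Naip1, an inflammasome receptor gene, had log2 fold changes of 7.86, 7.47, 7.57 and 8.09. Log2 ratios, with both papillomas, without papilloma 1 and without papilloma 2, were for Ltf 8.01, 9.47 and 7.30. Serpinb9 and Naip genes lie in families of near-identical copies, so their values are uncertain as single-gene values.

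The 12 called genes with the deepest falls in the tumour against papilloma included Krt1 and Klk5. Klk5, which encodes a protease of skin shedding, fell from 255 ± 19.5 to 1.78 CPM, and Hrnr, the hornerin gene of the cornified layer, from 1057 ± 128 to 9.21 CPM (edgeR adjusted p = 0.00205 and 0.00227). The secreted phospholipase gene Pla2g2f fell from 206 ± 14.2 to 1.66 CPM and the peroxidase gene Lpo from 91.4 ± 14.4 to 0.734 CPM. Mt4, a metallothionein of stratified epithelium, was at 15.3 and 53.4 CPM in the papillomas and 0.166 CPM in the tumour, and the lipoxygenase gene Alox8 at 39.1, 148 and 0.805 CPM. Chi3l4, a chitinase-like gene, and Ear5, an eosinophil-associated ribonuclease gene, had log2 fold changes of -7.62 ± 0.85 and -7.48 ± 0.62. Wfdc12, Them5 and Abhd12b fell with log2 fold changes from -6.78 for Wfdc12 to -6.75 for Abhd12b. Both papillomas, leaving out papilloma 1 and leaving out papilloma 2 gave log2 ratios for Mt4 -5.71, -6.34 and -4.57; Alox8 -6.17, -6.83 and -4.92; and Chi3l4 -7.52, -8.03 and -6.72. Chi3l4 and Ear5 have near-identical copies that could share reads.

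Some keratinocyte lists held mostly falls in the tumour and others mostly rises. Of 19 epidermal differentiation genes, 15 fell and 0 rose over all genes (0 up and 16 down adjusted over the list alone; median log2 ratio -5.02, percentile 0 of random lists). Krt10 fell from 9594 ± 1767 to 94.3 CPM. In the stress keratin and cornified envelope list 9 of 15 fell and 0 rose (0 up and 10 down adjusted over the list alone; median log2 ratio -1.65, percentile 0). Defb3 was at -4.96 ± 0.58 and S100a8, the other calprotectin subunit gene, at -2.54 ± 0.38. Simple and mucosal keratins had 4 up and 1 down of 8 (6 up and 1 down adjusted over the list alone; median log2 ratio 3.96, percentile 100). Krt7, Krt8 and Krt18 rose by 7.02 ± 0.29, 5.99 ± 0.29 and 4.07 ± 0.16. Krt13 was at 1065 and 236 CPM in the papillomas and 4624 CPM in the tumour, and this difference did not pass (edgeR adjusted p = 0.0735). Basal keratinocyte genes had 4 up and 0 down of 12 (7 up and 1 down adjusted over the list alone and 8 up and 1 down by DESeq2 over all genes; median log2 ratio 0.78, percentile 99.94). The laminin subunit gene Lama3 rose by 1.43 ± 0.27. Epithelial junction genes had 1 up and 4 down of 16 (1 up and 4 down adjusted over the list alone and 2 up and 6 down by DESeq2 over all genes; median log2 ratio -0.32, percentile 13.4). The desmocollin gene Dsc3 was at -1.71 ± 0.28, and Cdh1, encoding E-cadherin, at 719 ± 31.6 CPM in papilloma and 782 CPM in the tumour. Mesenchymal and EMT genes rose in 6 of 14 cases and fell in 0 (8 up and 0 down adjusted over the list alone; median log2 ratio 0.79, percentile 99.93). The transcription factor gene Snai2 and the fibronectin gene Fn1 rose by 1.90 ± 0.18 and 1.64 ± 0.21. Markers of other cell types rose in the same tumour library, 9 of 13 macrophage and monocyte genes and 5 of 11 neutrophil genes, while fibroblast and fibrillar matrix genes had a median log2 ratio of 0.37 (2 up and 3 down of 13). On the log2 scale, ratios with both papillomas, without papilloma 1 and without papilloma 2 were for Defb3 -4.75, -5.18 and -4.13.

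**Figure D2:**
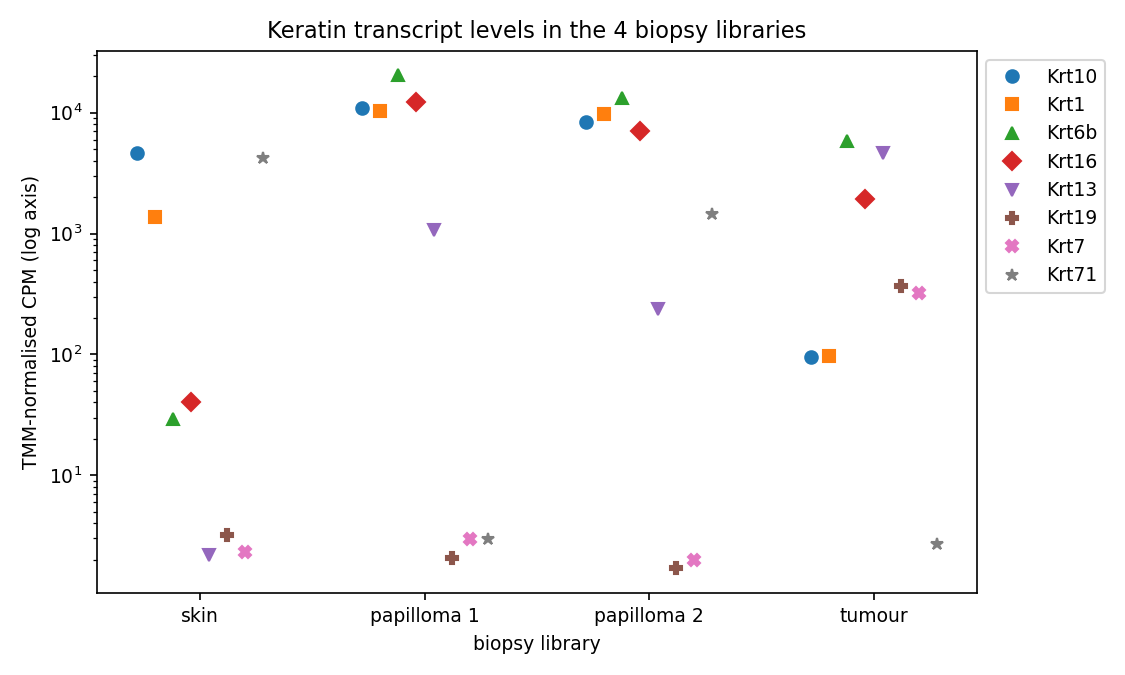
TMM-normalised CPM (y axis, log axis) of 8 keratin genes in each of the 4 biopsy libraries (x axis); each point is 1 library, offset sideways by gene. Krt10 lies at 94.3 CPM in the tumour against 10844 and 8345 CPM in papilloma 1 and papilloma 2, Krt19 at 371 against 2.07 and 1.70 CPM, and the hair keratin gene Krt71 is high in skin and papilloma 2.

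Most immune lists held more rises than falls in the tumour against papilloma. Macrophage and monocyte genes rose in 9 of 13 cases and fell in 0 (10 up and 0 down adjusted over the list alone; median log2 ratio 1.01, percentile 100). The integrin gene Itgam rose from 15.99 ± 0.367 to 80.8 CPM. Of 14 interferon response genes, 6 rose and 0 fell (7 up and 0 down adjusted over the list alone; median log2 ratio 1.05, percentile 99.99). The chemokine gene Cxcl9 and the regulator gene Irf7 led, at 4.85 ± 0.27 and 4.04 ± 0.21 (edgeR adjusted p = 0.00227 and 0.00227). The immune checkpoint and antigen presentation list had 5 up and 0 down of 11 (5 up and 0 down adjusted over the list alone; median log2 ratio 0.84, percentile 99.9). Cd274, encoding PD-L1, was at 12.1 ± 1.78 CPM in papilloma and 29.4 CPM in the tumour. Inflammatory cytokine genes had 8 up and 2 down of 17 (10 up and 3 down adjusted over the list alone and 8 up and 1 down by DESeq2 over all genes; median log2 ratio 1.09, percentile 100). The neutrophil chemokine gene Cxcl5 was at 3.93 ± 0.18 and Tslp, a cytokine gene of keratinocytes, at -4.08 ± 0.74. Neutrophil genes had 5 up and 0 down of 11 (7 up and 1 down adjusted over the list alone; median log2 ratio 1.77, percentile 100). The growth factor receptor gene Csf3r rose by 2.62 ± 0.25. T and NK cell genes had 5 up and 0 down of 13 (5 up and 0 down adjusted over the list alone; median log2 ratio 0.81, percentile 99.5). The cytotoxic granule gene Nkg7 was at 0.359 ± 0.0429 CPM in papilloma and 4.59 CPM in the tumour. In the B and plasma cell list, 2 rose and 0 fell of 4 (2 up and 1 down adjusted over the list alone and 1 up and 0 down by DESeq2 over all genes), with Igj, the immunoglobulin joining chain, at 5.53 ± 0.42. The MHC class II and dendritic cell list had 1 up and 1 down of 10 (1 up and 1 down adjusted over the list alone; median log2 ratio 0.40, percentile 93.8), against 3 up and 1 down by DESeq2. Itgax rose by 2.18 ± 0.19 and the Langerhans cell gene Cd207 fell by 4.67 ± 0.45. Mast cell genes had 0 up and 4 down of 9 (0 up and 5 down adjusted over the list alone; median log2 ratio -1.37, percentile 0.02), with Cpa3 at -2.13 ± 0.22. Ratios with both papillomas, without papilloma 1 and without papilloma 2, as log2 values, were for Tslp -3.58, -4.10 and -2.76.

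The signalling and stress lists held both rises and falls in the tumour. Ras MAPK output genes had 7 up and 0 down of 16 (7 up and 1 down adjusted over the list alone and 6 up and 1 down by DESeq2 over all genes; median log2 ratio 0.54, percentile 99.7). The MAP kinase phosphatase gene Dusp4 rose from 9.07 ± 1.06 to 93.2 CPM. Matrix protease and inhibitor genes had 5 up and 0 down of 14 (6 up and 0 down adjusted over the list alone; median log2 ratio 0.60, percentile 99.9, and 1.54 without papilloma 1 and 0.23 without papilloma 2), with Mmp12 at 2.83 ± 0.22. In the p53 target and cell cycle inhibitor list 4 rose and 1 fell of 12 (6 up and 3 down adjusted over the list alone and 5 up and 3 down by DESeq2 over all genes; median log2 ratio 0.60, percentile 99.4). The neighbouring genes Cdkn2a and Cdkn2b rose by 2.90 ± 0.17 and 2.29 ± 0.13. Proliferation genes had 1 up and 0 down of 20 (1 up and 0 down adjusted over the list alone; median log2 ratio -0.17, percentile 11.8), against 1 up and 1 down by DESeq2. The riser by edgeR was Ccnd1, at 1.52 ± 0.23. Hair follicle stem and tumour initiating genes had 3 up and 2 down of 11 (4 up and 3 down adjusted over the list alone; median log2 ratio 0.49, percentile 97.5), with the stem cell receptor gene Lgr6 at 4.32 ± 0.33. Wnt genes had 3 up and 3 down of 12 (3 up and 4 down adjusted over the list alone; median log2 ratio -0.95, percentile 0.06, and -0.93 without papilloma 1 and -0.12 without papilloma 2). Dkk3 was at 1.52 ± 0.15 and Axin2 at -1.18 ± 0.24, whose call was lost with total-count scaling. Of 9 Notch genes, 2 rose and 0 fell (2 up and 0 down adjusted over the list alone and 3 up and 0 down by DESeq2 over all genes; median log2 ratio 0.32, percentile 90.8), the ligand Jag1 and the target Hes1 being the risers by edgeR. Hypoxia and glycolysis genes had 1 up and 1 down of 14 (0 up and 1 down adjusted over the list alone; median log2 ratio 0.20, percentile 86.7; median -0.05 without papilloma 2), against 0 up and 2 down by DESeq2. Oxidative stress NRF2 genes had 2 up and 2 down of 12 (2 up and 2 down adjusted over the list alone and 3 up and 3 down by DESeq2 over all genes; median log2 ratio -0.13, percentile 29.9). AP-1 and immediate early genes had 0 up and 1 down of 11 (0 up and 0 down adjusted over the list alone; median log2 ratio -0.15, percentile 26.1; median 0.22 without papilloma 1).

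Appendage and stromal genes completed the tumour comparison. Sebaceous gland genes fell in 9 of 12 cases and rose in 0 (1 up and 10 down adjusted over the list alone and 1 up and 10 down by DESeq2 over all genes; median log2 ratio -2.19, percentile 0), with the fatty acid hydroxylase gene Fa2h at -4.18 ± 0.22. Hair follicle and shaft genes had 0 up and 1, Foxn1, down of 21 (0 up and 1 down adjusted over the list alone and 0 up and 3 down by DESeq2 over all genes), with a median log2 ratio of -5.80 (percentile 0) that was -6.79 without papilloma 1 and -0.34 without papilloma 2, the library that held hair transcripts. Melanocyte genes had 0 up and 0 down of 8 by edgeR (0 up and 0 down adjusted over the list alone; 0 up and 2 down at an unadjusted p under 0.05, 0 and 1 by DESeq2; median log2 ratio -3.62, percentile 0; -4.55 without papilloma 1 and -1.30 without papilloma 2). Tyrp1, a pigment enzyme gene, was at 2.25 CPM in papilloma 1, 37.8 in papilloma 2 and 0.616 in the tumour. With members at 0 counts set to their bound, the melanocyte median was -3.95. Of 14 skeletal muscle genes, 1 fell and 0 rose (0 up and 8 down adjusted over the list alone and 0 up and 7 down by DESeq2 over all genes; median log2 ratio -1.21, percentile 0), the fallen gene by edgeR being the creatine kinase Ckm at -1.79 ± 0.37, a call lost with DESeq2's size factors. Adipocyte genes had 3 down and 0 up of 12 (0 up and 3 down adjusted over the list alone and 0 up and 5 down by DESeq2 over all genes; median log2 ratio -0.37, percentile 8.94; -1.07 without papilloma 1 and -0.38 without papilloma 2), with the hormone-sensitive lipase gene Lipe at -2.10 ± 0.34. Fibroblast and fibrillar matrix genes had 2 up and 3 down of 13 (4 up and 3 down adjusted over the list alone; median log2 ratio 0.37, percentile 96.5), against 4 up and 3 down by DESeq2. The fibrillin gene Fbn1 rose by 1.13 ± 0.18 and Lum, a small proteoglycan gene, fell by 2.14 ± 0.19. Endothelial genes had 0 up and 1 down of 10 (0 up and 1 down adjusted over the list alone; median log2 ratio -0.24, percentile 10.2), the fallen gene being the angiopoietin receptor Tek. Erythrocyte genes had 0 and 0 of 6 by edgeR (0 up and 0 down adjusted over the list alone; median log2 ratio 0.37, percentile 89.4), with 0 up and 0 down at an unadjusted p under 0.05, 0 and 0 by DESeq2. Of 2 sex linked genes, 1 rose and 0 fell (1 up and 0 down adjusted over the list alone), Xist being at 2242 CPM in the tumour. Of 2 skin microRNA precursors 0 rose and 0 fell by edgeR (0 up and 0 down adjusted over the list alone; 0 up and 0 down at an unadjusted p under 0.05, 0 and 0 by DESeq2). The call of Xist was lost with DESeq2's size factors.

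The comparison of the tumour with healthy skin spans the whole course, with 1 library on each side and therefore values without a test. Krt13, a mucosal keratin gene (chromosome 11, 99978911 to 99982809), was at 2.20 CPM in skin and 4624 CPM in the tumour. Ltf was at 1.27 and 2018 CPM and Psca, a surface antigen gene of glandular epithelia, at 1.41 and 2032 CPM. The skin levels of Krt13, Ltf and Psca were 0.0475%, 0.0629% and 0.0694% of the tumour's, within the background of up to 0.0855%, so their ratios are lower bounds. Ppbp, the chemokine Cxcl7, was at 7.23 and 2904 CPM, Mmp13 at 1.43 and 1142 CPM, and Alox15, a lipoxygenase gene, at 0.403 and 229.5 CPM. Sprr3, Tmprss11bnl, Cxcl3, Krt6b, Sprr2k and Krt4 completed the 12 highest log2 ratios, from 9.17 for Sprr3 to 7.45 for Krt4. The skin values of Sprr3 and Sprr2k, 0.0873% and 0.0891% of their highest library, lay near background. The 12 lowest were all hair genes: Krt25, an inner root sheath keratin (chromosome 11, 99177159 to 99184255), was at 2872 CPM in skin and 1.42 CPM in the tumour. Krt71, Krt28, Krt27, Krt34, Krtap14, Krtap11-1, Krtap7-1, Krtap8-1, Krtap22-2, Krtap3-1 and Krtap15 had log2 ratios from -10.38 to -9.71. Their tumour values, from 0.0248% of skin for Krt28 to 0.0889% for Krtap15, lay at or near the level read as background. That level was set from hair genes in this tumour among other libraries, so these values cannot show on their own that they are a floor. If they are, larger differences would read alike. By the size rule 579 genes were higher and 1016 lower, against 451 and 1262 with total-count scaling. That scaling moved the median log2 ratio of genes at 10 CPM or more from 0.10 to -0.21. The difference has no replicate check, and the Krtap and Sprr genes lie in families whose copies could share reads.

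Of the lists, those of inflammation and matrix degradation were higher in the tumour than in skin. Inflammatory cytokine genes had a median log2 ratio of 4.02 (15 of 17 at least 2-fold higher, 1 lower). Matrix protease and inhibitor genes were at 3.51 (11 of 14, 1 lower). Simple and mucosal keratins were at 6.64 (5.46 with every member that had a count), neutrophil genes at 3.87 (2.72), stress keratin and cornified envelope genes at 4.15, Ras MAPK output genes at 2.29 and basal keratinocyte genes at 2.26, each at percentile 100 of random lists. Hair follicle and shaft genes were at -8.87, with tumour values near the level read as background, and melanocyte genes at -5.38 (-6.02 with 0 counts at their bound). Skeletal muscle genes were at -4.04, sebaceous gland genes at -3.85, epidermal differentiation genes at -3.40 and adipocyte genes at -3.01. Each of these lists with a negative median lay at percentile 0. Interferon response genes were at 0.67 (percentile 99.2), proliferation genes at 0.70 (percentile 99.7) and hypoxia and glycolysis genes at 1.22 (percentile 99.96). Macrophage and monocyte genes, at 0.38 (percentile 87.1), and T and NK cell genes, at 0.15 (percentile 91.8), lay in the central 95%.

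The comparison of mSCC-38 with mSCC-20 asks how highly tumorigenic cells differ from non-tumorigenic ones, with 1 library of each and no test. Of 14 mesenchymal and EMT genes, 11 were at least 2-fold higher in mSCC-38 and 0 at least 2-fold lower. Vim, the gene of the intermediate filament vimentin (chromosome 2, 13495939 to 13504453), was at 1.62 CPM in mSCC-20 and 3977 CPM in mSCC-38, the lower value being at background (0.0408% of the higher). Conversely, Cdh1, encoding the adhesion protein E-cadherin (chromosome 8, 109127269 to 109194146), was at 195 CPM in mSCC-20 and 1.62 CPM in mSCC-38, 120.3-fold (95% interval 92.04 to 160.3) lower. The tight junction gene Cldn4 was 703-fold (95% interval 450.2 to 1169) lower, and Esrp1, an epithelial splicing regulator gene, was at 60.9 and 0.391 CPM, the lower value being at background (0.0789% of its highest library). The basal keratin genes were abundant in both cultures, Krt5 at 9202 and 3733 CPM and Krt14 at 6611 and 3045 CPM in mSCC-20 and mSCC-38. By the size rule 666 genes were at least 4-fold higher and 324 at least 4-fold lower in mSCC-38, around a median log2 ratio of -0.16 for genes at 10 CPM or more (-0.04 with total-count scaling). The difference has no replicate check, and it compares 1 library of each culture, from the same or from separate tumours.

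The 12 genes of the highest ratios in mSCC-38 included Cd34 and Fgfr1 beside Vim. Cd34, a surface marker of hair follicle stem cells, was at 0.617 CPM in mSCC-20 and 677 CPM in mSCC-38, and the receptor gene Fgfr1 at 0.227 and 268 CPM. Lgi2, a secreted protein gene, had 0 counts in mSCC-20 and 118 CPM in mSCC-38, at least 1209.7-fold higher. Slit2, an axon guidance ligand gene, had 1 count in mSCC-20 and was 4443-fold (95% interval 797 to 175512) higher, and the chemokine gene Cx3cl1, with 3 counts, 2224-fold (95% interval 761 to 10787) higher. Dio2, which encodes an enzyme activating thyroid hormone, had 3 counts in mSCC-20 and 144 CPM in mSCC-38, 1475-fold (95% interval 504 to 7154) higher. Cp (ceruloplasmin), Stmn2, Sostdc1, Fbn1 and Aldh3a1 had log2 ratios from 8.44 for Cp to 7.94 for Aldh3a1. Among the lowest, Rab25, an epithelial vesicle traffic gene, was at 325 and 0.391 CPM, and Fgfbp1, a growth factor carrier gene, 367-fold (95% interval 279.8 to 492) lower. The chemokine gene Ccl20 was at 73.04 and 0.0602 CPM, 1214-fold (95% interval 336 to 10032) lower from 2 counts in mSCC-38. Csf2, a myeloid growth factor gene, also had 2 counts in mSCC-38 and was 950.0-fold (95% interval 263 to 7851) lower. Rps6ka6 and Ppp2r2c had 3 counts each in mSCC-38 and were 1107-fold (95% interval 378 to 5370.2) and 805-fold (95% interval 275 to 3907) lower, and Tmem47, with 2, 956-fold (95% interval 264 to 7900.0) lower. Mal, Myh10, Pdpn and Esx1 had log2 ratios from -7.27 for Mal to -6.61 for Esx1. The lower values of Slit2, Cx3cl1, Dio2, Fgfr1, Fbn1, Rab25, Ccl20 and Mal were at background, from 0.0225% of the highest library for Slit2 to 0.0848% for Fgfr1, so larger differences would read alike. Those of Rps6ka6, Cd34, Stmn2, Tmem47, Csf2 and Cp lay just above it, from 0.0903% for Rps6ka6 to 0.114% for Cp. The intervals cover counting error only.

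Lists in the cultures were set apart by their medians alone, without a test. The mesenchymal and EMT list had a median log2 ratio 4.37, percentile 100 of random lists. The transcription factor gene Prrx1 was at 2.18 and 363 CPM and Zeb2 at 0.357 and 72.01 CPM. Fibroblast and fibrillar matrix genes were 2-fold higher in 9 of 10 (median log2 ratio 3.97, percentile 100; 2.49 with every member that had a count). The collagen gene Col1a1 was at 2.18 and 122 CPM. Epithelial junction genes were 2-fold lower in 10 and higher in 1 of 16 (median log2 ratio -1.91, percentile 0). AP-1 and immediate early genes were lower in 9 and higher in 1 of 11 (median log2 ratio -3.06, percentile 0). Fos was at 236 CPM in mSCC-20 and 4.78 CPM in mSCC-38. Of 16 inflammatory cytokine genes, 9 were lower and 4 higher (median log2 ratio -1.10, percentile 0), Tnf being at 58.97 and 0.301 CPM. Stress keratin and cornified envelope genes had a median of -1.05 (percentile 0.37; -0.46 with every member that had a count). Sprr1b was at 353 and 10.3 CPM. Ras MAPK output genes were higher in 7 and lower in 5 of 16 (median log2 ratio 0.88, percentile 99.99). Dusp4 was at 9.94 and 83.2 CPM and Dusp5 at 64.2 and 3.37 CPM. Wnt genes were higher in 5 and lower in 0 of 7 (median log2 ratio 4.33, percentile 100; 0.62 with every member that had a count). Dkk3 was at 0.585 and 145 CPM. Interferon response and sebaceous gland genes had medians of 2.51 and 1.80, and -0.03 and -0.17 with every member that had a count, so their direction rested on which members were included. Basal keratinocyte genes had a median of -0.02 (percentile 77.98) and proliferation genes a median of -0.40 (percentile 21.6).

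**Figure D3:**
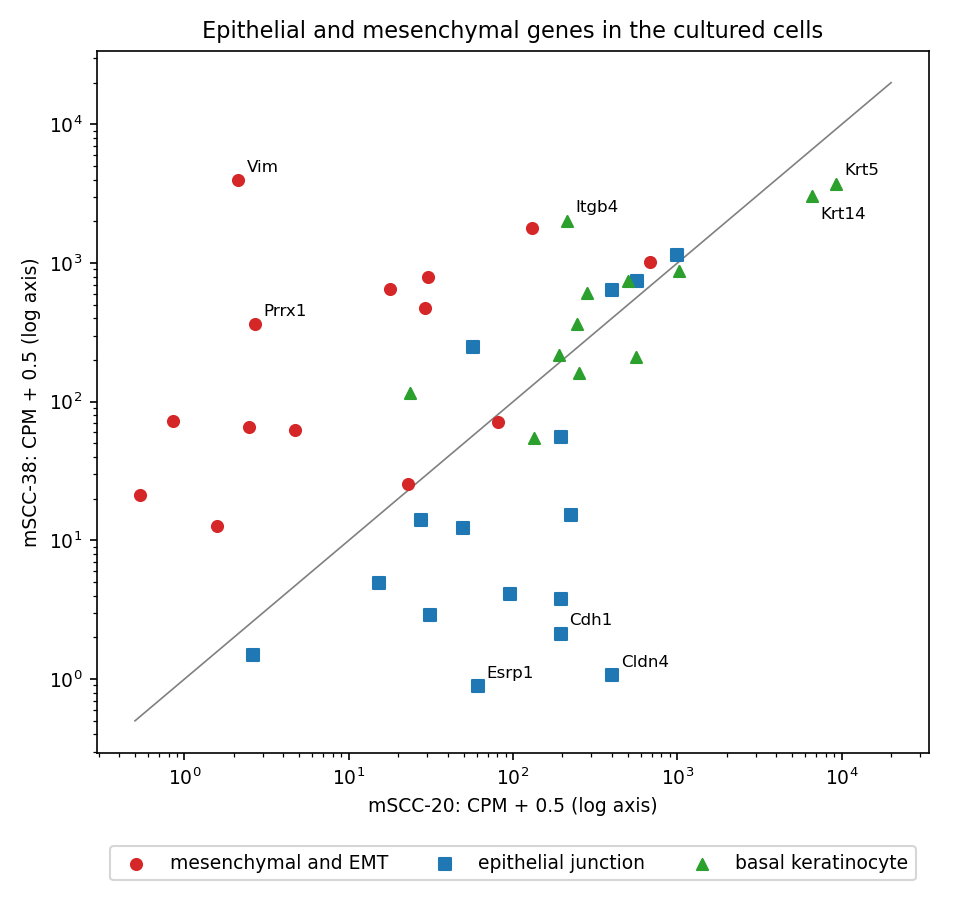
TMM-normalised CPM plus 0.5 in mSCC-20 (x axis, log axis) and mSCC-38 (y axis, log axis) for members of the mesenchymal and EMT, epithelial junction and basal keratinocyte lists; each point is 1 gene and the line marks equal values. Vim lies at 1.62 and 3977 CPM and Cdh1 at 195 and 1.62 CPM in mSCC-20 and mSCC-38.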

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

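Every alternative here was fixed before the counts were seen. The number of genes that edgeR called for papilloma against skin, 4257, lay between 3212 with DESeq2's size factors and 5011 without a filter on low counts, and for tumour against papilloma, 3687, between 3008 and 4292 under the same settings. DESeq2's Wald test called 4082 and 3701 genes, of which 3484 and 3208 were also edgeR's and in the same direction. Under the size rule the counts were 944 for papilloma against skin (734 without papilloma 1, 1084 without papilloma 2), 810 for tumour against papilloma (849 and 759), 1595 for tumour against skin (1402 to 2200) and 990 for mSCC-38 against mSCC-20 (873 to 1475), all within 1.5 times. No call could be tested with either papilloma left out, because no residual degree of freedom remained. No paired analysis was possible because only papilloma had more than 1 library. List medians that stood apart from random lists kept their sign under DESeq2's size factors and without either papilloma; with every member that had a count, the sebaceous gland list went from 1.80 to -0.17 and the interferon response list from 2.51 to -0.031 in mSCC-38 against mSCC-20, and the added members were those under 1 CPM; the cause was not tested. The largest shift without 1 library was in the hair follicle and shaft list. Of 65 called genes named for papilloma against skin, 6 lost their call with DESeq2's size factors and 2 with total-count scaling, and of 64 for tumour against papilloma 2 and 1 did, all at an unchanged direction; Krt5 gained one. Depth limits genes with few counts: in mSCC-20 a count of 0 allows 0.0975 CPM.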

Other observations

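The genes and chromosomes of the next sentences were chosen after their values were seen. Cdkn2a, the p16 and p19 tumour suppressor gene (chromosome 4, 88920378 to 88940523, mm9), had 0 counts in mSCC-38 and 734 counts in mSCC-20, at least 264-fold lower, while its neighbours Mtap and Cdkn2b were at 820.2 and 5.87 CPM in mSCC-38 and 357 and 2.27 CPM in mSCC-20. In the tumour Cdkn2a had 4066 counts. Ptplad2, also on chromosome 4, had 0 counts in mSCC-20 and 193 in mSCC-38, at least 59.6-fold higher. Xist, transcribed from an inactive X chromosome, was at 2.37 CPM in mSCC-20 and 473 CPM in mSCC-38, and at 985, 777, 998 and 2242 CPM in skin, papilloma 1, papilloma 2 and tumour. Of 17 hair genes with at least 500 CPM in skin, the median level was 0.0522% of skin in papilloma 1, 23.5% in papilloma 2, 0.0649% in the tumour, 0.0669% in mSCC-20 and 0.0438% in mSCC-38. The labels do not say whether both cultures came from the same tumour or mouse. Between the cultured cells, the median log2 ratio of mSCC-38 over mSCC-20, centred on all genes, was -0.54 for chromosome 19, 0.36 for chromosome 15 and 0.32 for chromosome 18.

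Among the tests of the 3 patterns below, those on hair genes in papilloma 2 and on mSCC-38 were chosen after the result was seen; those on chromosome 1 were written before their values, but the pattern had been noticed in these data and its median was known. Genes on chromosome 1 were higher in the tumour than in the papillomas: over 678 genes with a mean of at least 5 CPM the median log2 ratio, centred on all genes, was 0.51, with 76.3% of genes higher, against -0.22 to 0.14 for the other chromosomes; it was 0.53 against papilloma 1 and 0.53 against papilloma 2. A few strongly changed genes could not give this, since a median with 76.3% of genes higher does not rest on them. Without genes changed 2-fold the median was 0.36, with 0.12 the highest other chromosome, but this outcome was all but fixed in advance. Bias of GC content or gene length was argued against, since the median was 0.46 after adjustment, with 0.12 the highest other. A candidate explanation is an extra copy of much, but not the whole, of chromosome 1 in tumour cells: 83.3% of its segments of 10 Mb (15 of 18) had a median above 0.3, a bound set with the chromosome's median in view. The exceptions, starting at 100000001, 180000001 and 190000001, had medians of -0.22, 0.08 and -0.34 over 18, 43 and 30 genes, while 3 copies against 2 in every cell would give 0.58. Other segments lay above that value, such as those starting at 50000001 (0.73 over 53 genes) and 150000001 (0.75 over 40 genes). The genes of the chromosome had quartiles of 0.04 and 0.95, and the error of a segment's median was not estimated. Whether these medians exceed what 1 extra copy would give therefore cannot be told. An extra copy stays a hypothesis, as no DNA was measured and there was 1 tumour.

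Hair genes were abundant in papilloma 2 and near absent in papilloma 1. The excess of papilloma 2 over papilloma 1, as a percent of the skin level, had a median of 24.2% over the 21 hair genes (quartiles 21.0% to 28.9%). Reads or RNA of the skin library as the only source were argued against, because skeletal muscle genes, which that RNA would bring along, lay in papilloma 2 at only 11.3% of the skin level (quartiles 10.1% to 12.3%); a smaller part from that source stays open. Hair follicles within the papilloma 2 biopsy may be the source: melanocyte genes, from a separate list and near absent in papilloma 1, had an excess of 36.3%, positive in 8 of 8. Sebaceous gland genes, at a median of 44.7% of the skin level in papilloma 2, did not gain alike. Their median excess was 2.06% (quartiles -0.73% to 10.2%), positive in 8 of 11. Papilloma 1, where hair genes were near absent, held the sebaceous gland list at a median of 42.5 CPM. It was at 41.8 CPM in papilloma 2 and 54.5 CPM in skin. The list thus did not follow the hair genes in these lesions, and its small excess cannot test whole follicles with their glands. The source of the hair transcripts stays open.

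Mesenchymal genes were higher and junction genes lower in mSCC-38 than in mSCC-20. Fibroblasts in the culture as the only cause would lower alike all genes that fibroblasts do not express. The median log2 ratios of basal keratinocyte genes (-0.02) and epithelial junction genes (-1.91) differed by 1.89. This goes against that cause only if fibroblasts do not express the basal list genes, which was not tested. Of 100000 random splits of the pooled genes 2.10% lay as far apart, but genes are not replicates and each culture had 1 library. The bound on the basal median was reworded after its value was known. The basal keratins Krt5 and Krt14 were themselves lower in mSCC-38, with log2 ratios of -1.30 and -1.12. Fibroblasts as a source of the mesenchymal transcripts therefore stay open beside keratinocytes that gained such transcripts. Whether the difference goes with the tumorigenic state or with these particular cultures cannot be told apart, since there was 1 library, and so 1 culture, of each.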
